A study of Oncorhynchus mykiss with 16 samples.

How the data were processed

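The samples were whole ovaries of rainbow trout at 5 stages, 3 biological replicates at each stage and 4 at the mature stage, per the labels. Per the labels' protocols, total RNA was extracted with Tri-Reagent and purified on a column because of the yolk content, 150 ng of it was amplified and labelled with Cy3, and 600 ng of labelled cRNA was hybridised to each array. The arrays carried 1 colour. They lay on 2 slides, and every stage was present on both.

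The authors deposited the scanner output of each array, whose spot intensity values were made with Agilent Feature Extraction. The submitters' processing notes give version 10.5.1.1, while version 10.7.3.1 stands in the file headers. Per the file headers, the processed signal is an intensity on a linear scale. The authors also deposited a table of log2 values, 1 value per probe and array. Set against the scanner files, each column of it equalled the log2 processed signal averaged over the spots of a probe, minus 1 constant per array that brought the 75th percentile to 10.55. Its direction and scale were therefore settled by comparison. The medians of its columns lay between 7.65 and 7.95.

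The processed signals were converted to log2, the spots of a probe were averaged, and the 75th percentile over the non-control probes of an array was subtracted. Control spots were left out, as were 104 spots flagged as non-uniform or population outliers over all arrays. No non-control spot was saturated. Of 60195 probes, 49284 (81.9%) were well above background on every array of at least 1 stage and were tested. Limma 3.58.1 in R 4.3.3 was fitted to all 16 arrays with 1 coefficient per stage, followed by eBayes and Benjamini-Hochberg adjustment over the probes tested. A call means an adjusted p under 0.05. The comparisons were the moderated F test over all stages and the 4 differences between successive stages, and ± after a difference gives limma's SE where so stated. Some called probes were not well above background on every array of the lower stage. For part of these a fold bound is given, and for the others only levels or log2 differences. Bounds for stages with some such arrays were a choice made after the data were seen. The mean of the brighter stage was then set against the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. A bound therefore holds for stage means, not for each array or each slide. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

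The same fit was tested on simulated data, with 200 of 49203 probes changed by known amounts. Of 4-fold changes it recovered 48% for mid-vitellogenesis against immature, 62% for late against mid-vitellogenesis, 68% for post- against late vitellogenesis and 62% for mature against post-vitellogenesis. Of 2-fold changes it recovered 1%, 2%, 3% and 6% in the same order. False calls numbered 6, 4, 2 and 5. Noise was drawn independently for each probe and array, and few probes were changed. The figures therefore do not describe a step with many changed probes, or noise shared between probes.

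Most probes on the array are named only by an assembled sequence, and gene names were not analysed for these. A gene table for the species matched 4 of the 7 probes that carry a RefSeq accession, and 3 of the 4 had a gene symbol. A further 54 probes carry a gene or protein name in the scanner files, some of them cut short at the first space, and these are printed as given. All 58 named probes were examined whatever their values. They were sorted into groups by name once the names were known and before levels by stage were examined, so the groups were not fixed beforehand, and GR was kept as given because it has several readings. The 24 gene lists fixed before the data were examined matched at most 1 member each, so that no list reached the 5 members needed and the tests of lists were not run. Genes were to be named by a fixed rule. For each comparison it took the 8 largest rises and 8 largest falls among genes with a symbol, past an adjusted p of 0.05, with non-overlapping replicates and above background on every array of the higher stage. Members of called lists and a panel of ovarian genes were to follow. For probes without a symbol the rule takes 2 rises and 2 falls by probe identifier, and this was applied here. The named groups with at least 5 probes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, an addition made after the data were seen.

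The following alternatives were planned before the data were examined. They were quantile normalization, median centring, the 75th percentile over probes detected on all arrays, scaling on the E1A spike-in probes, normexp background correction with an offset of 50, the authors' log2 values, no filter on dim probes, only probes detected on all arrays, a trended and robust spread, array weights, only the 2 stages compared, slide or replicate number as a block, and each array left out in turn. The normexp correction used the median signal of each spot and of its local background. Array weights were estimated gene by gene, since the default method did not converge, and immature replicate 1 had a weight of 8.56 against 0.24 to 1.74 on the other arrays. Spike-in scaling used the median deviation over the E1A probes. Fits within each slide, array brightness as a covariate, and comparisons of stages that do not follow each other were added after the data were seen.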

Results

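Transcript levels were measured in whole ovaries of the rainbow trout, Oncorhynchus mykiss, at 5 stages of ovarian development. The series asked how the ovarian transcriptome changes between these stages. Ovaries were taken before yolk deposition (immature fish of 5 months), at mid-vitellogenesis, late vitellogenesis and post-vitellogenesis, and in mature females in which meiotic maturation was under way. Vitellogenesis is the phase in which the oocyte takes up yolk precursors from the blood. There were 3 biological replicates at each stage except the mature stage, which had 4, and each of the 16 samples was hybridised to its own array. Between 72.6% and 86.1% of the non-control spots of an array were well above background. Mature replicate 1 was the dimmest array, with a 75th percentile of 426 signal units against 961 to 3228 on the other arrays. The number of arrays limits the precision of each comparison.

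Immature ovaries stood apart from the ovaries of the 4 later stages. In limma's moderated F test, 17882 of 49284 probes differed among the 5 stages, and 51.4% of these had their highest mean in immature ovaries. The highest mean lay at mid-vitellogenesis for 14.8%, at late vitellogenesis for 9.7%, at post-vitellogenesis for 9.6% and at the mature stage for 14.5%. Immature ovaries also held the lowest mean most often, for 38.6% of these probes, against 10.6% to 22.9% at the other stages. The count of probes that differed was 10025 without immature replicate 1 and 10976 without immature replicate 2. It was 20230 without the dim mature replicate 1. With spike-in scaling 6312 probes differed, 5119 of them highest in immature ovaries and 158 at mid-vitellogenesis, and with array weights 32702 differed. Probes highest at post-vitellogenesis numbered 1712, against 918 and 1109 without immature replicates 1 and 2, 2795 without post-vitellogenesis replicate 1 and 2653 without mature replicate 1.

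**Figure D1:**
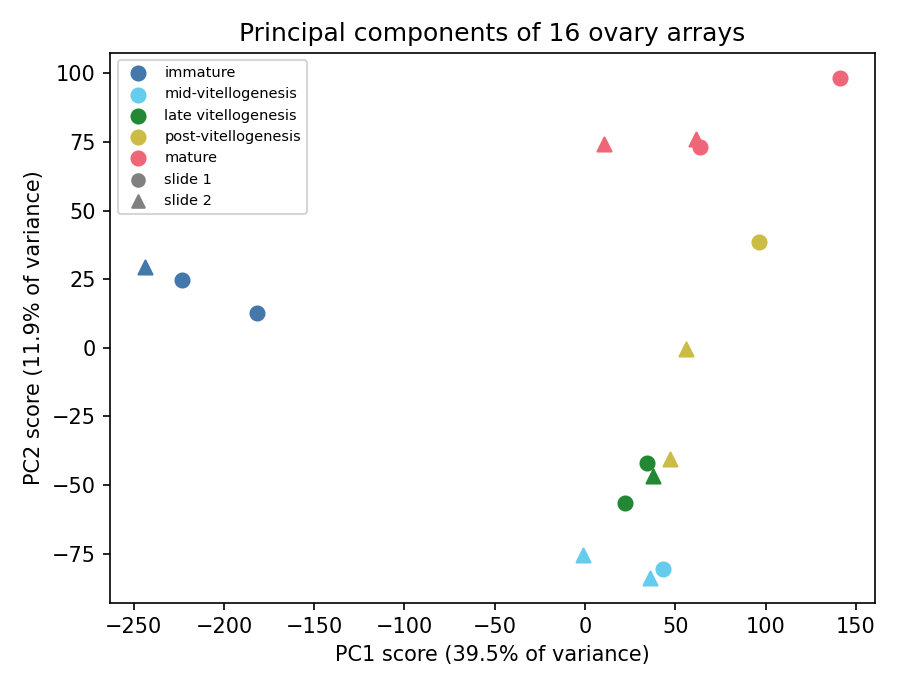
Scores of the 16 arrays on the first (x axis, 39.5% of variance) and second (y axis, 11.9% of variance) principal components of the log2 levels of all tested probes without an excluded spot; colour gives the stage and marker shape the slide. The immature arrays lie between -243.6 and -181.6 on PC1 and all other arrays at -1.1 or above, and on PC2 the mid-vitellogenesis arrays are lowest and the mature arrays highest.

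Probes with legible gene names numbered 58, and 46 of them were bright enough to be tested. The F test called 19 of these 46. VLDL, a name cut short in the array design, went from -2.26 ± 0.63 (SD, n = 3) in immature ovaries to -4.21 ± 0.33 (SD, n = 4) at the mature stage, on a log2 scale on which the 75th percentile of each array is 0 (limma F test, adjusted p = 0.0039). LC3B, a protein of the autophagosome membrane, went from 1.19 ± 0.30 (SD, n = 3) to 2.5 ± 0.51 (SD, n = 4) between the same stages (adjusted p = 0.025). Calpastatin, the inhibitor of calpain proteases, had its highest mean at late vitellogenesis, 3.44 ± 0.28 (SD, n = 3), and its lowest in immature ovaries, 1.91 ± 0.62 (SD, n = 3; adjusted p = 0.035). None of these 3 was called in a comparison of successive stages.

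Of the 46 named probes, 5 rose and 9 fell between immature and mid-vitellogenic ovaries, and camera called no group of at least 5 of them. The superoxide dismutases SOD1 and SOD2 fell by 1.18 and by 0.86 on the log2 scale, and HPGPX1, a glutathione peroxidase by its name, fell by 1.37. The probe named lipoprotein, a name cut short in the array design, rose by 5.06 ± 1.17 (SE), from -2 ± 0.71 to 3.05 ± 0.84 (SD, n = 3 each). The ubiquitin ligase subunit fbx32 rose by 1.39, while the fast-muscle light chain fast mlc1 fell by 2.49 and the myogenic factor myf5 fell from -2.95 ± 1.08 to -6.59 ± 1.73.

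Of the 8 antioxidant probes, 3 fell, none rose and 5 were not called, and 3 were called when adjusted over the list alone. SOD1 stood at 5.64 ± 0.51 in immature ovaries and at 4.46 ± 0.16 at mid-vitellogenesis (SD, n = 3 each; SE of the difference 0.27; limma adjusted p = 0.0051). HPGPX1 went from 5.65 ± 0.46 to 4.28 ± 0.19 (SE 0.24; adjusted p = 0.001), and SOD2 from 2.52 ± 0.32 to 1.66 ± 0.17 (SE 0.21; adjusted p = 0.0066), a call lost with only the 2 stages fitted. Catalase (log2 difference 0.06, SE 0.58) and GPX1 (0.02, SE 0.31) were not called. As a set, the 7 antioxidant probes without an excluded spot were not called against the other probes (camera, adjusted p = 0.42; adjusted p = 0.64 with an estimated correlation).

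Of the 10 probes for protein breakdown and autophagy, 1 rose and 2 fell, and 3 were called when adjusted over the list alone. Fbx32 rose from -0.76 ± 0.53 to 0.63 ± 0.10 (SD, n = 3 each; adjusted p = 0.0012). PSMA1, a subunit of the 20S proteasome, fell by 0.79 (SE 0.27; adjusted p = 0.035), and atg4b, the protease that processes LC3, fell by 0.82 (SE 0.23; adjusted p = 0.016). PSMA1 lost its call without immature replicate 1 or 2, without any of the 3 mid-vitellogenesis replicates, with quantile normalization, with the percentile over detected probes and with only the 2 stages fitted. Atg4b lost it without immature replicate 2, with normexp and with only the 2 stages fitted. Camera did not call this group (adjusted p = 0.83; adjusted p = 0.87 with an estimated correlation).

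Of the 13 probes tested for glucose and lipid metabolism, 3 rose, 1 fell and 9 were not called, with 4 called when adjusted over the list alone. Besides the lipoprotein probe (adjusted p = 0.0055), the rises were hexokinase, which phosphorylates glucose, and ATP-citrate, a name cut short in the array design. Hexokinase was not well above background on any immature array, and mid-vitellogenic ovaries were at least 1.65-fold higher (adjusted p = 0.0034). ATP-citrate rose by 1.36 (SE 0.44; adjusted p = 0.029), a call lost without immature replicate 2 or 3, without mid-vitellogenesis replicate 2 or 3, with quantile normalization and with median centring. L-3-hydroxyacyl-CoA, also cut short, fell by 0.91 (SE 0.23; adjusted p = 0.0092). Its call was lost with quantile normalization and with only the 2 stages fitted, and the hexokinase call with normexp. The median of the 13 differences was -0.22 and their mean 0.42, and camera did not call the group (adjusted p = 0.83; adjusted p = 0.87 with an estimated correlation).

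Of the 8 muscle and mesoderm probes tested, 2 fell, 1 rose and 5 were not called, with 4 called when adjusted over the list alone. Fast mlc1 went from -1.32 ± 0.75 to -3.81 ± 1.05 (SD, n = 3 each; SE 0.49; adjusted p = 0.0022). Of the 3 mid-vitellogenesis arrays, 2 measured myf5 above background, and the fall between the stage means was at least 7.42-fold (limma adjusted p = 0.005). Its log2 difference was -2.30 within slide 1 and -5.13 within slide 2, with the value below background taken as measured. Fast myosin (-0.06, SE 0.60) and fast mlc3 (-0.27, SE 0.78), also transcripts of fast muscle, were not called. Wnt4b, a secreted Wnt ligand, rose by 0.97 (SE 0.31; adjusted p = 0.025) and lost its call without immature replicate 1 or 2 or mid-vitellogenesis replicate 2 or 3, and with quantile normalization or median centring. Spike-in scaling turned it to -0.16. Camera did not call this group (adjusted p = 0.42; adjusted p = 0.64 with an estimated correlation). Of the 4 nuclear receptor probes tested, PPARa, a receptor for fatty acids, fell by 0.76 (SE 0.26; adjusted p = 0.038), and the other 3 were not called. The PPARa call was lost without immature replicate 1 or 2, mid-vitellogenesis replicate 1 or 3, or late-vitellogenesis replicate 1, and with the percentile over detected probes, normexp, no filter on dim probes or only the 2 stages fitted.

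**Figure D2:**
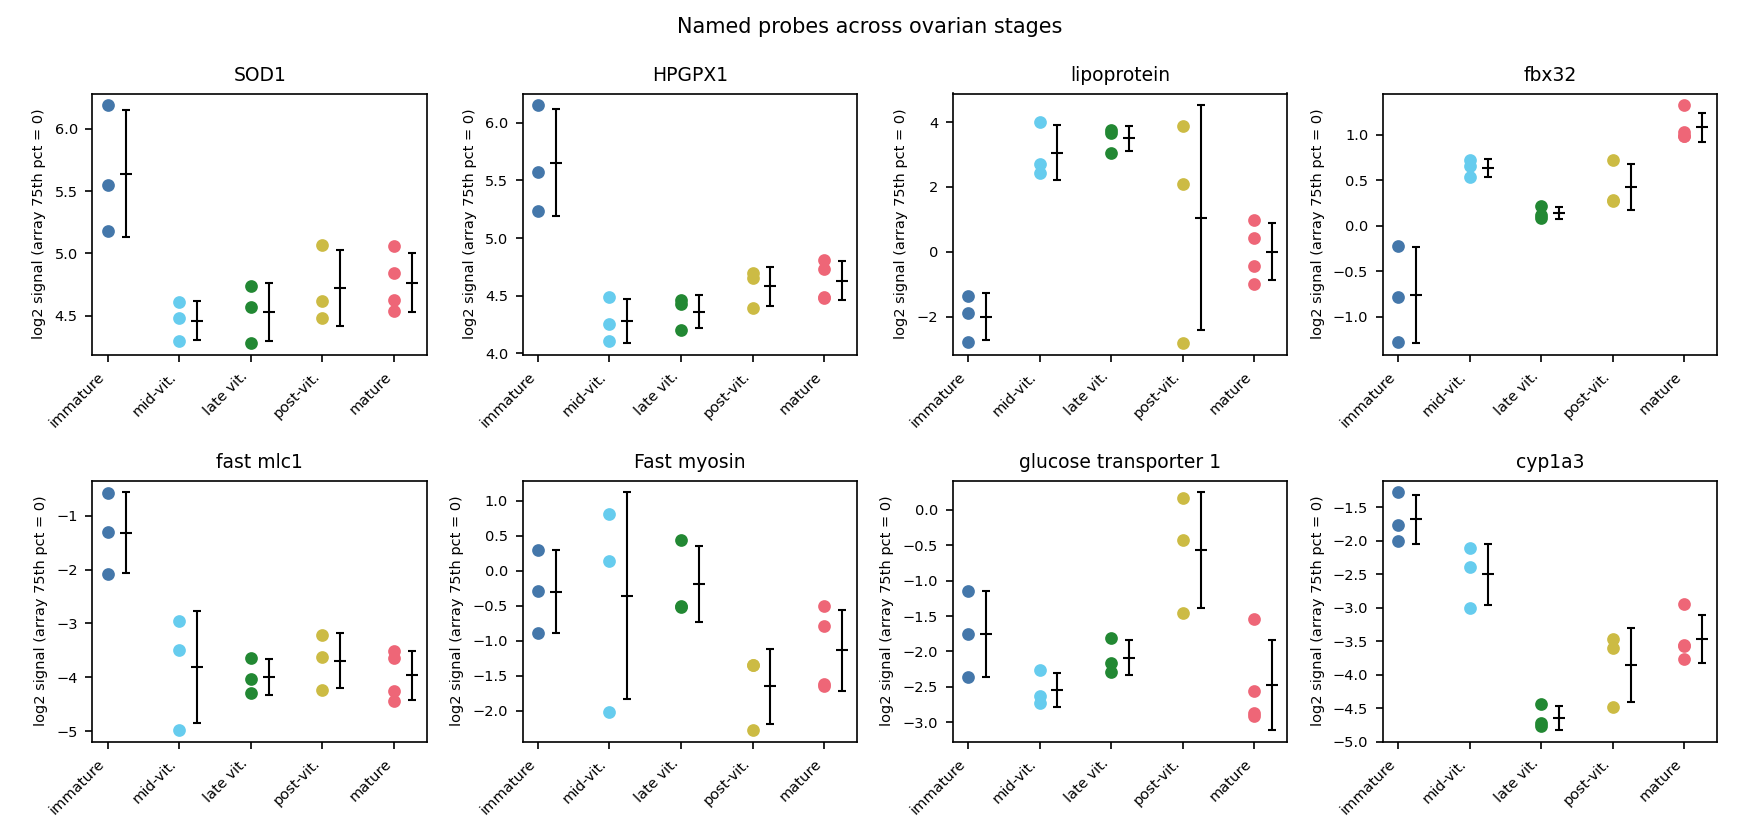
Log2 signal of 8 named probes (y axis, array 75th percentile at 0) by stage (x axis); filled points are arrays on which the probe was well above background, and the bars give mean ± SD of 3 arrays per stage, or 4 at the mature stage. SOD1 and HPGPX1 are highest in immature ovaries, the lipoprotein probe averages -2 in immature ovaries and 3.49 at late vitellogenesis, and cyp1a3 is lowest at late vitellogenesis (-4.65).

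Over all probes tested, 7651 were higher and 8799 lower at mid-vitellogenesis than in immature ovaries (16450 in all, limma), and 12542 of them differed at least 2-fold. At mid-vitellogenesis CUST_15451_PI425536763 was at least 5390-fold higher (adjusted p = 5.5e-08) and TC101285 at least 6050-fold higher (adjusted p = 5.8e-08), both well above background on 1 of the 3 immature arrays. TC122929 was at least 251-fold lower at mid-vitellogenesis (adjusted p = 0.0015), where neither it nor CUST_11472_PI425536763 was well above background on any array. CUST_11472_PI425536763 stood at 1.11, -1.96 and 1.44 on the 3 immature arrays (adjusted p = 0.023). Neither probe was uniform within the later stages. TC122929 stood at 1.43 on mature replicate 4, within its immature range of 1.18 to 1.65, and below background on the other mature arrays. CUST_11472_PI425536763 stood at 1.75 on late-vitellogenesis replicate 3 and at 1.24 and 1.72 on post-vitellogenesis replicates 1 and 3, but below background on late-vitellogenesis replicate 2. The files pair none of these 4 probes with a gene name. CUST_11472_PI425536763 lost its call without immature replicate 1 or 3 or any mid-vitellogenesis replicate. With the slide as a block 17354 probes were called, and within slide 1 and slide 2 alone 1381 and 6568. Higher probes were the majority within slide 1 (932 to 449), within slide 2 (3505 to 3063) and with the 75th percentile over probes detected on all arrays (9056 to 7175). With the arrays scaled on spike-in RNA the median difference over all probes was -1.16 and 465 probes were higher against 6868 lower. On that scale the lipoprotein probe rose by 3.92 (limma adjusted p = 0.035). Over its alternatives apart from the fits within slides, its adjusted p lay between 7.9e-05 and 0.035. HPGPX1, SOD1, L-3-hydroxyacyl-CoA, myf5 and fast mlc1 also kept their calls on the spike-in scale. These were all falls, which the shift of that scale enlarged by construction (SOD1 from -1.18 to -2.31). SOD2 (-1.99), PPARa (-1.89), PSMA1 (-1.92), atg4b (-1.95), fbx32 (0.26), hexokinase, ATP-citrate (0.23) and Wnt4b (-0.16) were not called on the spike-in scale. Within slide 1 alone only the lipoprotein and fast mlc1 probes were called of the 14, and within slide 2 alone PPARa, SOD2, atg4b, hexokinase and the lipoprotein probe were not.

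Late vitellogenesis differed from mid-vitellogenesis in 37 probes, 1 of them named. Cyp1a3, a cytochrome P450 induced through the aryl hydrocarbon receptor, fell by 2.15 (SE 0.33; limma adjusted p = 0.027), from -2.5 ± 0.45 to -4.65 ± 0.18 (SD, n = 3 each). No other of the 46 named probes was called, so that no antioxidant, protein breakdown, metabolism or muscle probe passed the test at this step. SOD1 (0.07, SE 0.27), fbx32 (-0.49, SE 0.25) and the lipoprotein probe (0.44, SE 1.17) gave differences that were not called. The cyp1a3 call was lost with the slide as a block (adjusted p = 0.055; 0.003 to 1 over its alternatives), with spike-in scaling (-1.74), normexp, only the 2 stages fitted, the replicate block, within either slide alone, and without mid-vitellogenesis replicate 2 or 3 or any of the 3 late-vitellogenesis replicates.

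Over all probes, 11 were higher and 26 lower at late vitellogenesis, and all 37 differed at least 2-fold. Higher probes were the majority within slide 1 (11 to 5) and with only the 2 stages fitted (12 to 8). CUST_14402_PI425536763 fell by 8.15 (SE 0.81; adjusted p = 0.0015), from 4.90 ± 0.99 to -3.25 ± 0.48 (SD, n = 3 each). CUST_45_PI425708691 fell by 6.61 (SE 1.10; adjusted p = 0.043). TC124664 rose by 4.83 (SE 0.80, adjusted p = 0.043). TC100224 was not well above background on any mid-vitellogenesis array. Its stage mean rose at least 9.67-fold, to -3.30 ± 0.50 (SD, n = 3, limma adjusted p = 0.036). Its log2 differences of 2.66 within slide 1 and 6.19 within slide 2 were taken against values below background. The calls of CUST_45_PI425708691, TC124664 and TC100224 were lost with the slide or replicate as a block and with only the 2 stages fitted, and were each lost in 10 of the 16 fits that left out 1 array. No filter on dim probes also ended the first 2, array brightness as a covariate the first, only probes above background on all arrays the second and normexp the third. Within either slide alone none of the 4 was called, CUST_14402_PI425536763 included. Over all probes the differences within the 2 slides correlated at 0.31. The count was 21 with the slide as a block. It was 18 without late-vitellogenesis replicate 2 and also without replicate 3, 23 without post-vitellogenesis replicate 2, 24 without mature replicate 2, and 81 without post-vitellogenesis replicate 1.

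Between late and post-vitellogenesis no probe was called, named or unnamed. Glucose transporter 1, which carries glucose across the cell membrane, stood at -2.09 ± 0.25 at late vitellogenesis and at -0.57 ± 0.82 at post-vitellogenesis (SD, n = 3 each; log2 difference 1.52, SE 0.44; limma adjusted p = 0.71). The lipoprotein probe stood at 3.49 ± 0.40 and at 1.05 ± 3.46, and LDL, also a name cut short, at -2.28 ± 0.25 and at -0.23 ± 2.54. Among the 13 metabolism probes, 1 was called when adjusted over the list alone. The spread of the lipoprotein and LDL probes among the post-vitellogenic ovaries was larger than the difference between the stages. Limma gave 0 calls in 49284 probes, with a lowest adjusted p of 0.302. An unadjusted p under 0.05 was reached by 2307 probes, against 2464 expected by chance. It was reached by 21966 probes at mid-vitellogenesis against immature, 4356 at late against mid-vitellogenesis and 3868 at mature against post-vitellogenesis.

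The count at this step depended on the post-vitellogenic arrays. It was 49 without post-vitellogenesis replicate 3, 10 without replicate 2 and 1 without replicate 1, as well as 1 without late-vitellogenesis replicate 2 or mature replicate 2. With the slide as a block it was 0. Over all probes the differences within the 2 slides correlated at 0.2.

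Mature ovaries, in which meiosis had resumed, differed from post-vitellogenic ovaries in 239 probes, 167 of them higher and 72 lower (limma), but in no named probe. Which direction held the majority depended on single arrays. Glucose transporter 1 stood at -2.47 ± 0.64 (SD, n = 4) in mature ovaries against -0.57 ± 0.82 (SD, n = 3) at post-vitellogenesis (log2 difference -1.90, SE 0.41; adjusted p = 0.064). The probe named phosphoenolpyruvate, cut short in the array design, differed by -1.23 (SE 0.32; adjusted p = 0.15), and fbx32 by 0.66 (SE 0.23; adjusted p = 0.38). Of the 13 metabolism probes, 2 were called when adjusted over the list alone. Camera gave this group an adjusted p of 0.16 towards lower levels (adjusted p = 0.51 with an estimated correlation).

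Among the unnamed probes, CUST_120_PI425708691 rose to 6.45 ± 0.40 (SD, n = 4) in mature ovaries (adjusted p = 0.019). At post-vitellogenesis it stood at 3.25 in replicate 2, at -5.21 in replicate 3 and at -6.35, below background, in replicate 1, so that no single fold describes the difference. The log2 difference was 3.49 within slide 1 and 11.94 within slide 2, where the value below background of replicate 1 was taken as measured. TC124682 rose to 3.40 ± 2.13 (SD, n = 4; adjusted p = 0.0073), with 0.61 in mature replicate 1 and, at post-vitellogenesis, -2.59 in replicate 2 and values below background in the other 2. Its log2 difference was 5.63 within slide 1. The 10.93 within slide 2 was taken against the arrays below background. Between the stage means over both slides the rise was at least 326-fold, a bound that the difference within slide 1 did not reach. CUST_7223_PI425536763 fell to -5.30 ± 2.30 (SD, n = 4; adjusted p = 0.027), with -2.04 in mature replicate 2, and its difference was -5.99 within slide 1 and -4.82 within slide 2. CUST_23374_PI425536763 fell to -5.38 ± 1.49 (SD, n = 4; adjusted p = 0.033) from -3.36, 0.40 and 1.58 on the 3 post-vitellogenic arrays, with differences of -6.57 and -3.71 within the slides. Both were well above background on 3 of the 4 mature arrays. The call of CUST_120_PI425708691 was lost without post-vitellogenesis replicate 3 or mature replicate 3, and that of CUST_7223_PI425536763 without those or mature replicate 4, or with normexp. These 2 were lost with the replicate block, and all 4 with only the 2 stages fitted or within slide 1 alone. That of CUST_23374_PI425536763 was lost with the slide as a block, with quantile normalization, spike-in scaling or normexp, and in 13 of the 16 fits that left out 1 array.

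**Figure D3:**
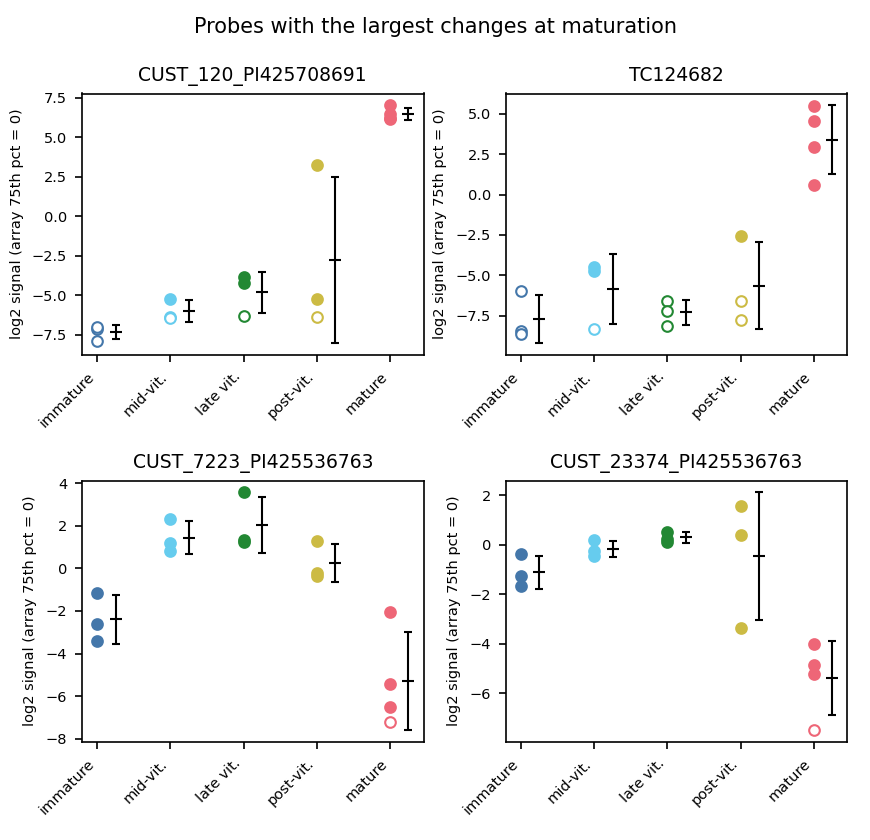
Log2 signal of 4 unnamed probes called at maturation (y axis, array 75th percentile at 0) by stage (x axis); filled points are arrays well above background, open points arrays that were not, and bars give mean ± SD of 3 arrays per stage, or 4 at the mature stage. CUST_120_PI425708691 averages -2.77 at post-vitellogenesis with an SD of 5.24 and 6.45 in mature ovaries with an SD of 0.40.

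Of the 239 probes, 237 differed at least 2-fold. With the slide as a block 216 probes were called, 203 of them among the 239. Over all probes the differences within the 2 slides correlated at 0.17. The count was 81 without post-vitellogenesis replicate 3, 493 without replicate 2 and 538 without replicate 1 (146 higher and 392 lower), and it was 130 without mature replicate 3 and 136 without mature replicate 4. Without the dim mature replicate 1 it was 321 (156 higher and 165 lower), and with array weights 867 (289 higher and 578 lower).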

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

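Control probes, which entered no comparison, gave signal above background, and no test of stage was run on them. Of 25 control probes of the ERCC and ETG sets, ERCC-00062_278 and ETG10_195139 were well above background on all 16 arrays. ERCC-00062_278 had a mean log2 level of 0.37 ± 0.70 (SD, n = 3) in immature ovaries, 2.78 ± 0.17 (SD, n = 3) at mid-vitellogenesis, 2.84 ± 0.27 (SD, n = 3) at late vitellogenesis, 3.52 ± 1.13 (SD, n = 3) at post-vitellogenesis and 3.52 ± 1.47 (SD, n = 4) at the mature stage, relative to the 75th percentile of each array. ETG10_195139 stood at -4.4 ± 0.89, -3.14 ± 0.78, -1.66 ± 1.94 and -2.5 ± 1.04 (SD, n = 3 each) at the same 4 stages and at -1.92 ± 1.29 (SD, n = 4) at the mature stage.

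Among the 4 mature arrays, 48 values were examined for a sample far from the others, and 5 had a gap to the nearest sample beyond Dixon's 95% critical value; chance gives about 1 in 20. Mature replicate 1 stood apart in the share of spots well above background (72.6%, against 81.0% to 82.7%), in MSS1 (4.36, against 3.97 to 4.03), in fbx32 (1.32, against 0.98 to 1.02) and in fast mlc3 (-3.65, against -0.67 to -0.12). Mature replicate 3 stood apart in the probe named carnitine (-3, against -3.95 to -3.88).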

How the results depend on the processing

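The number of calls rested on the scaling, the spread model and single arrays, and it moved with the treatment of background and of dim probes. Spike-in scaling takes 1 constant from each array, which moved the median difference over all probes at the first step from -0.03 to -1.16, so that rises smaller than this shift turned by construction.

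With spike-in scaling 6312 probes differed among the stages, 7333 at mid-vitellogenesis against immature, 15 at late against mid-vitellogenesis and 89 at mature against post-vitellogenesis. The highest means then lay at immature for 5119, mid-vitellogenesis for 158, late vitellogenesis for 366, post-vitellogenesis for 185 and mature for 484. The share of higher calls at the first step was 46.5%, against 6.3% with spike-in scaling, 34.5% with median centring, 55.8% with the percentile over detected probes, and 67.5% and 53.4% within slides 1 and 2. At late against mid-vitellogenesis it was 29.7%, against 60.0% with only the 2 stages compared, 68.8% within slide 1 and at most 45.1% with any other setting. At maturation it was 69.9%, against 27.1% without post-vitellogenesis replicate 1, 33.3% with array weights and 48.6% without mature replicate 1, and at most 91.7% with only the 2 stages compared. The Wnt4b difference turned to -0.16 by that shift (limma adjusted p 0.9, with a range of 0.00033 to 0.9 over its alternatives apart from the fits within slides). Spike-in scaling moved the median difference over all probes to 0.33, -0.69 and 0.22 at the later steps.

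Median centring and normexp put the highest mean at mid-vitellogenesis for 1665 and 1534 probes. Normexp gave 14 calls at late against mid-vitellogenesis and 115 at mature against post-vitellogenesis, and probes above background on all arrays gave 12 and 113, where fewer probes were tested. Only the 2 stages compared gave 20, 1 and 12 calls at the last 3 steps, with fewer arrays and a spread taken from those stages alone. That setting kept 5 of the 37 main calls at late against mid-vitellogenesis and 12 of the 239 at maturation. The main fit shared 1 spread over stages whose median SD over probes was 0.4, 0.3, 0.23, 0.37 and 0.42 in order. Whether fewer arrays or the spread lowered the counts was not tested. Array weights, which gave immature replicate 1 a weight of 8.56, gave 32702 probes differing among the stages and 27572, 565, 2 and 867 calls at the 4 steps. Highest means then lay at immature for 16331, mid-vitellogenesis for 5388, late vitellogenesis for 2771, post-vitellogenesis for 4240 and mature for 3972. For settings where no construction is named, the cause was not tested.

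The slide block gave 21 calls at late against mid-vitellogenesis. Within slide 1 alone, a setting added after seeing the data in which a lone sample is assumed to vary like the other stages, the 4 steps gave 1381, 16, 38 and 23 calls, and within slide 2 alone 6568, 3, 5 and 38. Replicate numbers did not pair the samples. Deviations of same-numbered samples correlated between -0.27 and 0.11, and 1 of 16 samples correlated best with its own number. The replicate block gave 18 calls at late against mid-vitellogenesis and 105 at maturation, and 16158, 15648 and 0 for the F test, the first step and the third.

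With each array left out in turn, probes that differed among the stages numbered 10025 to 20230, and the calls at the 4 steps 11040 to 18761, 18 to 81, 0 to 49 and 81 to 538. Highest means ranged from 4778 to 10118 for immature, 1523 to 3238 for mid-vitellogenesis, 1047 to 1931 for late vitellogenesis, 918 to 2795 for post-vitellogenesis and 1759 to 3475 for mature. Quantile normalization, the percentile over detected probes, the authors' values, no filter, and trended spread kept every count of calls within 1.5 times, as did array brightness as a covariate, added after seeing the data. Of 196 single-probe differences, 166 alternative values lost a call, 58 gained a call and 1 turned. Of 15 named calls, 6 were kept with spike-in scaling, 9 with only the 2 stages compared, and 10 to 15 with 1 array left out. The tests of the fixed gene lists, and the mean over several probes of a gene, were not run, since no list had 5 matched members and each named gene had 1 probe.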

Other observations

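The comparisons of stages that do not follow each other, the read-name prefixes, the fits within slides, the brightness tests, the positions between stages and the overlap of falls with rises were chosen after the results were seen, as was the use of scaling and single arrays as explanations.

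Mature ovaries differed from mid-vitellogenic ovaries in 1712 probes, 795 higher and 917 lower (limma). The count was 1064 without mid-vitellogenesis replicate 1, 663 without replicate 2 and 943 without replicate 3, and with any other array left out it lay between 1197 and 2391. Mature ovaries differed from immature ovaries in 20937 probes, 8320 higher and 12617 lower (15240 to 22097 with 1 array left out). They differed from late-vitellogenic ovaries in 916, 456 higher and 460 lower, against 283, 292 and 431 without late-vitellogenesis replicates 1 to 3, 1492 without post-vitellogenesis replicate 1, and 581 and 584 without mature replicates 2 and 3. Post-vitellogenic ovaries differed from mid-vitellogenic ovaries in 135 probes, 38 higher and 97 lower. That count was 88, 50 and 45 without mid-vitellogenesis replicates 1 to 3, 392 and 60 without post-vitellogenesis replicates 1 and 2, 75 without immature replicate 1, 85 without late-vitellogenesis replicate 2, and 218 and 89 without mature replicates 1 and 2. LOC100136786 and myod1 differed among the 5 stages (limma F test, adjusted p = 0.036 and 0.019) but were called at no single step. The same held for glucose transporter 1 (F test, adjusted p = 0.012), the probe named phosphoenolpyruvate (0.017) and LDL (0.05 as rounded, under the threshold before rounding). Of 1825 called probes that share 1 read-name prefix, 35.6% had their highest mean in immature ovaries, against 46.0% to 65.7% for the other 9 prefixes.

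The difference between immature and mid-vitellogenic ovaries was set against array scaling and slide. A single constant per array cannot give calls in both directions, and 465 probes were still called higher with spike-in scaling, which argues against scaling as the whole difference. With that scaling 1640 calls changed sign, a number set by the size of the shift that decides nothing, so the direction of the smaller rises stays open. With the slide as a block 15737 of the 16450 calls were kept, and over all probes the differences within the 2 slides correlated at 0.71, which argues against the slide. Stage and the age of the fish, given as 5 months for the immature group and not for the others, cannot be told apart here and remain untested.

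The count of 239 probes between mature and post-vitellogenic ovaries was set against post-vitellogenic ovaries lying at different points on the way to maturation. On probes called between mid-vitellogenic (0) and mature (1) ovaries, a choice that used no post-vitellogenic array, the probes higher at mature stood at 0.84 in post-vitellogenesis replicate 2, 0.32 in replicate 3 and 0.06 in replicate 1. The probes lower at mature stood at 0.67, 0.35 and 0.76 in the same ovaries, so that replicate 1 had the falls without the rises. The positions spanned 0.78 and 0.41 within post-vitellogenesis, against at most 0.40 and 0.28 within another stage, too few arrays to decide. They were not taken on the 239 probes, so they do not say what separated mature from post-vitellogenic ovaries in those. With array brightness as a covariate 226 of the 239 calls were kept. Mean brightness was similar at the 2 stages (log2 75th percentiles of 8.78 to 11.38 at mature and 9.95 to 10.36 at post-vitellogenesis). The covariate could therefore move the stage difference little, and this does not decide on brightness. The count did rest on single arrays (81 without post-vitellogenesis replicate 3).

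Of the 72 falls at maturation, 38 (52.8%) were among the rises of the first step, which held 15.5% of all probes, and independent lists would share 11.2. Sets of probes with the same level at post-vitellogenesis held 11.3 such probes on average and at most 26 in 10000 draws (permutation p = 1e-04, the smallest these draws can give), which argues against level as the source. These draws, and Fisher's exact test below, treat probes as independent. Their p-values therefore do not measure the variation between fish. With 1 array left out the share lay between 42.4% and 60.0%, against 10.6% to 18.0% of all probes, which argues against a single array for the share. The link to falls alone did rest on post-vitellogenesis replicate 2: without it 36 of 85 falls and 91 rises (62.4 by chance) had risen at the first step, and Fisher's exact p for the 2 directions was 0.21, against 4e-05 with all arrays. The counts moved to 22 of 43 without immature replicate 1, 185 of 392 without post-vitellogenesis replicate 1, 9 of 15 without replicate 3, and 96 of 165, 18 of 35, 18 of 31 and 15 of 30 without mature replicates 1 to 4, to 25 shared without immature, mid-vitellogenesis or late-vitellogenesis replicate 2, and to 6 of 15 with spike-in scaling.

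Within stages, the leading axis of variation followed array brightness over the 16 arrays, with 24.5% of the within-stage variance (Pearson r = 0.96, permutation p = 2e-04; Spearman rho = 0.91, permutation p = 6e-04, resampled within stages). Without mature replicates 1 and 4, the farthest from the median, r was 0.85.

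Other groupings of the same arrays were fitted as a check on chance, on probes without an excluded spot. Of 100 groupings of the 16 arrays, 1, the real grouping, gave as many as 17861 probes differing among the stages, and the highest other gave 12. Of 35 groupings of the mature and post-vitellogenic arrays, 1, the real grouping, gave as many as 239, and the highest other gave 157, with post-vitellogenesis replicate 3 placed among the mature arrays and mature replicate 1 among the post-vitellogenic ones. Of 35 groupings of the mature and mid-vitellogenic arrays the real 1 gave 1711 and the highest other 219, and for mature and late-vitellogenic arrays 914 and 73. For mature and immature arrays the real grouping gave 20902 and the highest other, which added mature replicate 4 to the 3 immature arrays, 12571. For these 5 results only the real grouping gave as many calls, a share under 0.05. With 35 groupings that share is the smallest possible, and shares were not adjusted over the results. Chance is thus argued against rather than excluded. At maturation 21 of the other groupings also gave calls. The 10 groupings possible for 3 against 3 arrays are too few for a share under 0.05. The real count was 16426 and the highest other 0 at mid-vitellogenesis against immature, and 37 and 5 at late against mid-vitellogenesis. At post- against late vitellogenesis they were 0 and 4, and since any grouping reaches a count of 0, this says nothing about chance. At post- against mid-vitellogenesis the real count was 135 and 2 of the 10 groupings gave as many. The other gave 148, with post-vitellogenesis replicate 1 and mid-vitellogenesis replicates 2 and 3, all on slide 2, against the rest, 2 of which were on slide 1. With the slide as a block the real count was 104.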
